A study of Homo sapiens with 8 samples.

How the data were processed

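RNA was measured in 8 libraries of human induced pluripotent stem (iPS) cells and of neurons induced from them (iN). Lentiviral vectors had brought dCas9-KRAB into the cells, a nuclease-dead Cas9 joined to a KRAB repressor domain. One arm also carried a guide RNA against LTR5_Hs, the long terminal repeat of the youngest HERV-K proviruses, and the control arm carried none. Transduced cells were kept under puromycin, and doxycycline switched on neurogenins to make the neurons. The libraries were stranded TruSeq mRNA libraries. The labels place them in 4 groups of 2: iPS cells with the guide, iPS cells without it, iN with the guide and iN without it.

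The deposited files hold raw read counts, as whole numbers with a different total in each library. Each library has counts for 63677 Ensembl gene IDs and for 4568653 repeat annotation lines with position, name, strand and class. The submitters' processing notes name HISAT2, featureCounts and the hg19 build. Tool versions, annotation releases, the strand setting and the handling of reads that map to several places are not given in the sources used here, so counts of genes with near-identical copies or an overlapping antisense gene are uncertain. Symbols and gene types came from GENCODE by Ensembl ID, which gave 52526 IDs a symbol. No gene positions on the build of the files were used, so the distance from genes to LTR5_Hs was not analysed here.

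In the files, 60459 repeat lines join several neighbouring pieces of one element. Each such line was assigned to its first internal part, or else to its first name, which gave 1172 subfamilies. Under this assignment LTR5_Hs stands for 566 lines without an internal part, and HERVK-int for 173 lines that include the merged proviruses. Of 614 lines with an LTR5_Hs piece, 48 were merged with HERVK-int.

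Genes and repeat subfamilies were filtered with edgeR's filterByExpr by group, which left 18863 genes and 1052 subfamilies. Single repeat loci needed at least 10 counts in at least 2 libraries, which left 23895. Gene counts were scaled with TMM, and repeat counts with the library sizes and TMM factors of the genes. One model with the 4 groups and no other term was fitted to all 8 libraries with edgeR 4.0.16 (quasi-likelihood, legacy option) in R 4.3.3. F tests were two-sided, Benjamini-Hochberg adjustment was applied within each comparison, and an adjusted p under 0.05 counted as passed. Adjusted p-values without another name come from this fit. The SE of a log2 fold change is its size divided by the square root of F. CPM are counts scaled to a common total of gene counts with TMM, also for repeats (edgeR cpm).

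5 gene comparisons were made: guide against control in iPS cells and in iN, iN against iPS cells without and with the guide, and the difference between the guide effects (interaction). For repeats, the last comparison with the guide was left out. 31 gene lists were fixed, and camera (limma 3.58.1) tested the 28 with at least 5 tested members. The inter-gene correlation was preset at 0.01, and the test was run again with an estimated one. The run with an estimated correlation also uses the few residual degrees of freedom of the design, so its p-values rise for that reason too. Proneural factors, with an estimated correlation of 0.00861, went from adjusted p = 2.1e-07 to 0.135 by camera in iN against iPS cells without the guide. The lists that passed in a guide comparison had estimates far above the preset value. These were 0.844 for mitochondrial genome transcripts, 0.761 for ribosomal protein genes, 0.740 for glycolysis, 0.195 for core pluripotency, 0.162 for cell cycle and 0.143 for p53 targets. If these estimates hold, the p-values of these lists at the preset value are too small. Camera also compared loci within 50 kb of annotated LTR5_Hs, LTR7 or SVA_D, SVA_E and SVA_F elements with other loci. Tests, lists, groups and the rule for named genes were set before the data were examined. That rule names, for the guide effects and their difference, the 10 largest rises and 10 largest falls among passing genes with an average log2 CPM of at least 0 (5 each way for iN against iPS cells). For the guide effects and for iN against iPS cells, both libraries of one group also had to lie above both of the other. It adds up to 4 members per list with the smallest p, and 8 fixed genes. Repeat subfamilies and loci were named by similar rules. Genes of the Y chromosome and XIST were never named, and some genes that the rule selects are not reported here.

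For a group with 0 counts, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 counts, the ratio is given with an exact 95% interval. These intervals and floors cover counting error only. The libraries held 15577927 to 23839714 gene counts. Tested on simulated data at these depths and sample numbers, the model recovered 64.2% of genes changed 1.5-fold, 71.6% changed 2-fold and 98.5% changed 4-fold in the iPS comparison, with 3.23% of calls false. In iN these were 77.6%, 77.6% and 89.4%, with 5.56% of calls false, and for the interaction 43.3%, 70.1% and 80.3%, with 3.21% false. For single repeat loci in iPS cells it recovered 0% at 1.5-fold, 11.9% at 2-fold and 62.1% at 4-fold, with 5.97% of calls false. For loci in iN the shares were 1.49%, 5.97% and 63.6%, with 1.79% false. The simulation left 18639 of 18863 genes and 22745 of 23895 loci unchanged. It used means over all groups and dispersions from a trend. In the data 62.4% of genes passed in iPS cells and 52.0% in iN, so recovery and false shares may differ there.

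The description labels give a guide arm and a number in both stages, so same-numbered iPS and iN libraries may share a line. The model used no such pairing. Across genes, the deviations of same-numbered libraries from their group means correlated between -0.0285 and 0.0308, which does not exclude a shared line. Nothing in the labels says that the libraries of a group are separate cultures, so p-values measure only the spread between these samples. No source ties a guide line to a control line of the same transduction, so the guide and a difference between transduced lines cannot be told apart. Alternatives were RLE scaling, other low-count filters, only the 2 groups compared, replicate or line as a block, repeat counts scaled by their own totals, DESeq2 1.42.0, a 2-fold minimum, an estimated correlation, other distances and each library left out in turn. The non-legacy fit, another assignment of merged lines and a stricter filter for loci near elements were added after seeing the data. With 2 libraries per group, no regrouping of samples and no search for outliers was made.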

Results

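The 8 libraries held 15577927 to 23839714 gene counts and 637304 to 1343798 repeat counts. Mitochondrial transcripts took 3.61% to 4.69% of gene counts. Libraries of one group correlated at r = 0.992 to 0.995 (log2 CPM across genes, which are not independent replicates), and the spread between them beyond counting error amounted to a coefficient of variation of 5.42%. Values with ± are means with the SD over the 2 libraries of a group.

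The first question was whether the target was lower in guide libraries. HERVK-int, the internal part of HERV-K proviruses, fell in guide iPS cells from 226 ± 25.7 to 52.6 ± 3.79 CPM (n = 2), a log2 fold change of -2.10 (SE 0.12, adjusted p = 2.5e-65). By library, the iPS controls had 208 and 244 CPM and the guide cells 55.3 and 49.9 CPM. In iN, HERVK-int fell from 86.2 ± 3.33 to 66.5 ± 0.00517 CPM (-0.37, SE 0.12, adjusted p = 0.0017), with 83.8 and 88.5 CPM in the controls and 66.5 CPM in both guide libraries. LTR5_Hs lines outside proviruses gave 25.3 and 28.6 CPM in iPS controls, 20.8 and 21.4 in guide iPS cells, 34.4 and 38.2 in iN controls and 38.2 and 33.1 in guide iN. Their log2 fold change was -0.36 in iPS cells (SE 0.13, adjusted p = 0.0122) and -0.02 in iN (SE 0.12, adjusted p = 0.845), or -1.07 in iN when repeat counts set the scale. The iPS call was lost without guide library 1 (adjusted p = 0.115), guide library 2 (0.0791) or control library 2 (0.199). With the 48 merged lines that hold an LTR5_Hs piece counted as LTR5_Hs, LTR5_Hs fell by 2.62 in iPS cells (adjusted p = 8.1e-94) and by 0.63 in iN (1.2e-07), while the remaining HERVK-int lines gave 0.08 in iPS cells (0.591) and 0.50 in iN (9.6e-05).

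**Figure D1:**
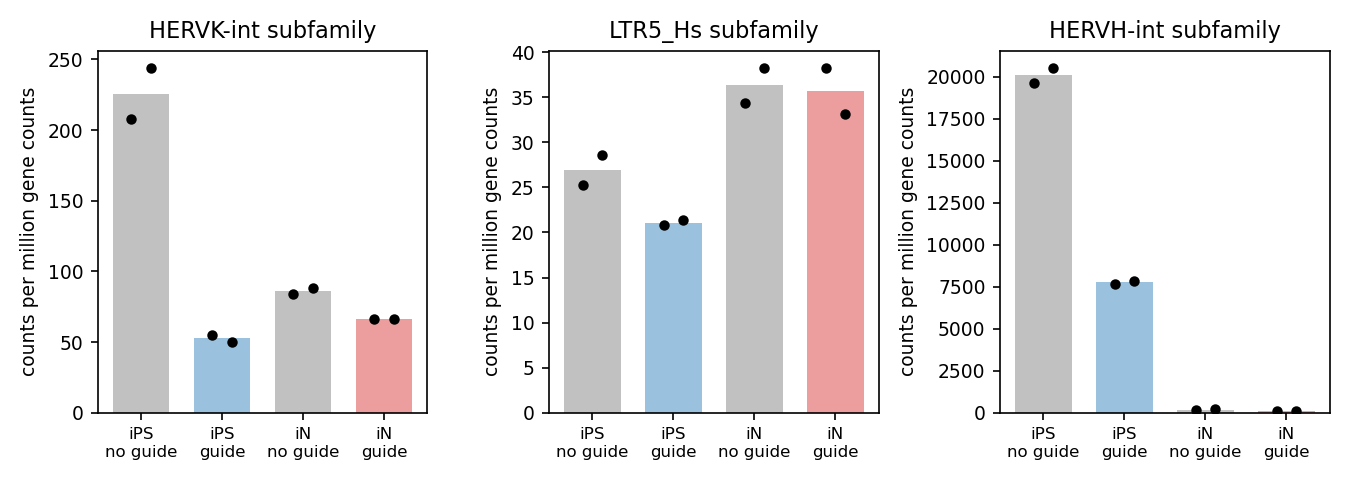
CPM of HERVK-int, LTR5_Hs outside proviruses and HERVH-int in the 4 groups, with bars for means and points for the 2 libraries. HERVK-int stood at 226 in iPS controls and 52.6 in guide iPS cells, and HERVH-int at 20087 and 7768.

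Most other repeat subfamilies moved the opposite way. Of 1052 tested, 586 were higher and 84 lower in guide iPS cells, with a median log2 fold change of 0.49, and 919 were higher and 15 lower in guide iN, with a median of 1.02. Scaled by the repeat counts instead, which sets the median near 0, the split was 258 higher and 259 lower in iPS cells and 141 higher and 240 lower in iN. More repeat loci held a count at equal gene depth in guide libraries: 274341 and 277164 against 163216 and 161140 in iPS cells, and 339049 and 285315 against 147647 and 156122 in iN. Relative to the median subfamily, HERVK-int lay at -2.59 in iPS cells and -1.39 in iN, LTR5_Hs at -0.85 and -1.04, and HERVH-int at -1.86 and -1.76. HERVH-int, an endogenous retrovirus active in pluripotent cells, fell in iPS cells from 20087 ± 617 to 7768 ± 110 CPM (-1.37, SE 0.11, adjusted p = 1.4e-30), as did its repeat LTR7 (-0.80, SE 0.13). In iN, HERVH-int went from 179 ± 23.8 to 107 ± 13.1 CPM (-0.74, SE 0.12), while of its 575 tested loci 62 fell and 21 rose, with a median of 0. Core pluripotency genes also fell in guide iN (median -1.67). Fewer remaining pluripotent cells in guide iN can therefore not be told apart from an effect of the guide on HERVH there. SVA elements, composite retroposons that contain an LTR5-derived part, were lower in iPS cells for SVA_B (-0.87), SVA_C (-0.98), SVA_D (-0.66), SVA_E (-0.78) and SVA_F (-0.41, a call lost without guide library 1 or control library 1, adjusted p = 0.145 and 0.0817), with SVA_A at -0.25 (adjusted p = 0.0735). In iN, SVA_A (-0.44), SVA_B (-0.78) and SVA_D (-0.31, lost without control library 2, adjusted p = 0.083) were lower, with values of 0.18 for SVA_C, 0.14 for SVA_E and -0.10 for SVA_F that did not pass, or -0.87, -0.91 and -1.15 with repeat-count scaling. L1HS, the youngest LINE-1 group, rose by 0.69 in iPS cells and 0.60 in iN, LTR5B by 0.55 and 0.52 and LTR5A by 0.65 in iN. With repeat-count scaling these turned to -0.44, -0.53 and -0.39 in iN, and LTR5B to 0.07 in iPS cells (adjusted p = 0.655).

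Single loci showed where the fall lay. Of the 19 tested HERVK-int lines joined to LTR5_Hs, 14 fell and 1 rose in guide iPS cells, with a median of -3.86, and 10 fell and 2 rose in iN, with a median of -2.64. Adjusted over the group alone, 15 and 14 changed. Of the 13 with LTR5_Hs on both sides, 12 fell in iPS cells and 8 in iN. Of 11 HERVK-int lines joined to the older LTR5A or LTR5B, 5 fell and 3 rose in iPS cells, and 0 fell and 5 rose in iN. The share that fell differed between these kinds of provirus in iN (Fisher's exact test, two-sided, p = 0.00405), and the iPS test did not pass (p = 0.238). This test treats loci of the same libraries as independent and holds no spread between libraries. Similar proviruses may also share reads and so move together. Of 22 LTR5_Hs loci without an internal part, 5 fell and 6 rose in iPS cells, and 2 fell and 2 rose in iN. The provirus on chromosome 22, 18926187 to 18935361 (hg19, plus strand), gave 58 counts with the guide and 4476 without in iPS cells (-5.81, SE 0.20, adjusted p = 1.2e-118), and 3 and 194 counts in iN, a ratio of 0.0166 (95% interval 0.0034 to 0.0493). In iPS cells the proviruses at 118591724 (-5.69, SE 0.29) and 101565794 (-6.28, SE 0.33) on chromosome 11 and at 156084717 on chromosome 5 (-3.86, SE 0.31) also fell, and the one at 185280336 on chromosome 3 had 2 counts against 205, a ratio of 0.0132 (0.00159 to 0.0484). In iN the provirus on chromosome 5 was at least 18.3-fold lower (0 against 59 counts), and those on chromosome 3 at 9889346 (-2.35, SE 0.24) and 101410737 (-1.43, SE 0.16) fell. An LTR5A provirus on chromosome 4 at 9659580 rose in iN (2.26, SE 0.24).

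**Figure D2:**
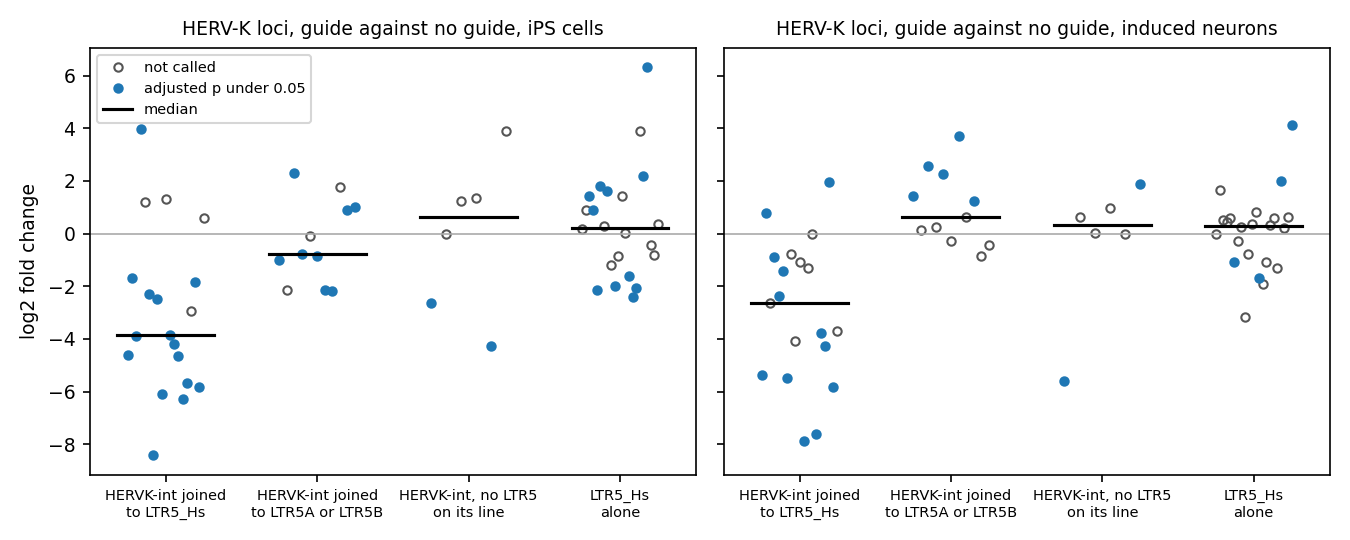
Log2 fold change, guide against no guide, of single HERV-K loci by the repeat joined to their internal part, in iPS cells and in induced neurons. Points are loci, filled where the adjusted p is under 0.05, and lines are medians, which lie at -3.86 and -2.64 for HERVK-int joined to LTR5_Hs.

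Across all 23895 tested repeat loci, 3420 rose and 3548 fell in guide iPS cells, and 5902 rose and 669 fell in guide iN, where the median was 0.62. With repeat-count scaling the split was 2149 and 5909 in iPS cells and 1040 and 3663 in iN. The iPS total of 6968 became 3517 without control library 1 and 2960 without control library 2, and the iN total of 6571 became 3281 without guide library 1 and 3982 without control library 2. DESeq2 called 3052 loci in iPS cells and 2049 in iN, and with a filter of 20 counts 3908 and 3569 passed. HERVH-int fell at 411 of 575 loci and rose at 14 in iPS cells, among them chromosome 5 at 126175029 (1178 counts against 12846), chromosome 5 at 120033241 (-2.61, SE 0.14) and X at 113701125 (-2.56, SE 0.15). The HERVH locus on chromosome 11 at 118587743, directly beside an LTR5_Hs provirus, went from 519 to 8 counts (-5.54, SE 0.32). SVA loci fell at 29 of 91 in iPS cells and 22 of 91 in iN, among them an SVA_A on chromosome 2 at 71387605 in iN (-2.69, SE 0.21). At loci other than LTR5_Hs and HERVK-int, the rises with the smallest p in iPS cells included an L1PA10 on chromosome 21 at 9827579 (3.68), an AluSx on chromosome 17 at 33477943 (3.38) and a HERVK9-int on chromosome 5 at 1577977 (3.66). In iN they included an L1PA14 on chromosome 4 at 191014420 (5.38) and an MLT1E3 on chromosome 5 at 17604304 (3.76).

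Whether the effect spread from the target was asked with the 950 tested loci of other kinds within 50 kb of an annotated LTR5_Hs. In iN their median stood at 0.38 against 0.63 at other loci, a difference of -0.25 (camera adjusted p = 0.00103, and adjusted p = 0.011 with an estimated correlation), and 7.68% of them fell against 2.46% of other loci. In iPS cells the difference was -0.13 and did not pass (adjusted p = 0.173), with 19.2% and 14.5% lower. These sets still held HERVH loci, which fell widely in iPS cells. Without HERVH and LTR7 loci, a set chosen after seeing the data, the difference was -0.10 in iPS cells (camera adjusted p = 0.372). In iN it was -0.22 (0.00286). This check was made at 50 kb only. Within 10 kb, the iPS difference was -0.27 (adjusted p = 0.0413), and near SVA_D, SVA_E or SVA_F it was -0.38 (adjusted p = 0.0313). Near LTR7 it was -0.34 (adjusted p = 0.0313, and adjusted p = 0.151 with an estimated correlation). At 200 kb, the iN difference was -0.17 (adjusted p = 0.0713). By distance, 8.33% of loci fell in iN at 0 to 10 kb, 7.46% at 10 to 50 kb, 4.30% at 50 to 200 kb, 2.02% from there to 1 Mb and 2.40% beyond. The loci near LTR5_Hs still differed by -0.24 in iN (adjusted p = 0.000142) when only loci with at least 10 counts in 2 iN libraries were compared, a set chosen after seeing the data. The loci within 50 kb of LTR7 gave -0.56 in iN (adjusted p = 0.00018), but 20.5% of them had no counts in iN and so a log2 fold change of 0. Among loci counted there the difference was -0.11 and did not pass (adjusted p = 0.252), nor did it with repeat-count scaling (0.19, adjusted p = 0.845). Loci near SVA_D, SVA_E or SVA_F gave -0.17 in iN (adjusted p = 0.0279) and -0.18 among counted loci (adjusted p = 0.00977), a call that ended with that scaling (adjusted p = 0.0514) and without the 279 loci also near LTR5_Hs, a set chosen after seeing the data (-0.12, adjusted p = 0.101).

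In iPS cells, many genes differed between guide and control libraries, whether through the guide or through the line: 5260 of 18863 were higher and 6506 lower with the guide, of which 1357 and 2745 changed at least 2-fold. PRODH (ENSG00000100033), which encodes proline dehydrogenase and has a reported HERV-K link, fell from 65.1 ± 7.34 to 1.90 ± 0.26 CPM (-5.10, SE 0.16, adjusted p = 2.1e-24). NTRK3, a neurotrophin receptor gene with such a link, stayed at 7.71 ± 0.00257 against 7.73 ± 0.232 CPM (adjusted p = 0.985). Among the largest falls, PLAAT5 went from 21.7 ± 2.87 to 0.28 ± 0.043 CPM (-6.27, SE 0.24), ANKRD33 was at least 47.0-fold lower (0 against 191 counts), LAPTM5 at least 8.11-fold, ALDH8A1 at least 6.64-fold, C1QL4 at least 6.15-fold and LMO1 at least 5.90-fold lower. LAMB2P1 had a ratio of 0.00997 (95% interval 0.00025 to 0.0565). TLX2 and SLC4A5 were at least 4.92-fold and 4.43-fold lower. ZSCAN5C was at least 30.3-fold higher, H3Y2, a primate histone H3 variant, at least 29.4-fold and SRSF8BP at least 28.9-fold higher, while TRIM48 had a ratio of 85.4 (14.8 to 3426) and TRIM49D2 of 52.9 (8.95 to 2141). SNORD3B-2 rose by 5.01 (SE 0.48), LINC01619 was at least 7.23-fold higher and GLRA2 at least 2.71-fold higher. Several of these belong to families with near-identical copies, so their counts may hold reads of other members.

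3 of the 28 tested gene lists passed camera in iPS cells. With an estimated correlation, which also cuts the degrees of freedom of the test, 0 passed. Glycolysis genes fell at 10 of 12 members and rose at 0 (10 adjusted over the list alone), with PDK1 at -2.01, PGK1 at -1.82 and LDHA at -1.75 (adjusted p = 0.00538, and adjusted p = 0.917 with an estimated correlation). Of 15 p53 targets, 12 fell and 3 rose (15 adjusted over the list alone), among them RRM2B (-1.50), CDKN1A (-1.29) and BTG2 (-1.38), with adjusted p = 0.0248 and adjusted p = 0.917 with an estimated correlation. With only the 2 groups fitted, this call ended (adjusted p = 0.0505). Transcripts of the mitochondrial genome rose at 10 of 13 and fell at 2 (12 adjusted over the list alone), led by MT-ND2 (1.29) and MT-ND3 (1.22). Their test gave adjusted p = 0.0248, adjusted p = 0.917 with an estimated correlation and adjusted p = 0.0545 without control library 2.

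The other lists did not pass as sets in iPS cells. Core pluripotency genes went both ways, 10 higher and 9 lower of 26 (19 adjusted over the list alone): NODAL (2.62), LEFTY1 (2.25) and L1TD1 (1.35) rose, LIN28A fell (-1.23), and POU5F1, the pluripotency factor OCT4, gave -0.12 (adjusted p = 0.152). Naive pluripotency genes split 1 and 4 of 9 (5 adjusted over the list alone), with NLRP7 at -4.64, and HERVH-driven transcripts 1 and 4 of 8 (5), with LINC00458 at -3.77 and ESRG at -0.71. Domesticated ERV genes split 2 and 3 of 5 (5), with ERVH48-1 at -2.63. Cell cycle genes split 13 and 6 of 24 (20), with RRM2 at 1.43 and TOP2A at -1.28. Mesoderm and endoderm markers split 5 and 1 of 9 (6), with AFP at 2.42 and CER1 at 2.30, and trophoblast and amnion markers 3 and 1 of 6 (4), with GATA2 at 3.15. Fibroblast and mesenchyme markers split 2 and 6 of 11 (8), with COL1A2 at -1.77 and TAGLN at 2.03. Pan-neuronal genes split 3 and 9 of 19 (12), with STMN2 at -2.48, proneural factors 2 and 5 of 18 (7), with ONECUT1 at -4.64, synapse genes 10 and 13 of 25 (23), with SV2B at -3.36, and axon guidance genes 4 and 12 of 25 (16), with ROBO2 at -2.19. Transmitter receptors and transporters split 3 and 8 of 22 (11), peripheral and sensory neuron genes 3 and 4 of 14 (7), neural progenitor genes 4 and 3 of 11 (7), with VIM at -2.13, and glial genes 2 and 8 of 13 (11), with MBP at -1.70. Interferon-stimulated genes split 1 and 11 of 15 (12), led by BST2 at -2.20, integrated stress response genes 6 and 7 of 15 (13), with DDIT4 at -2.78, heat shock genes 6 and 2 of 10 (8), with HSPH1 at 1.31, and immediate early genes 6 and 1 of 11 (7), with EGR1 at 0.91. Retroelement silencing genes split 5 and 6 of 14 (11), with ATF7IP at -1.18, and KRAB zinc finger genes 10 and 8 of 22 (19), with ZNF587 at -1.08 and ZNF93 at 0.93. ZNF10, whose KRAB domain is widely used in repressor fusions, rose by 0.80. Whether ZNF10 counts hold reads of the dCas9-KRAB vector was not tested. Nuclear OXPHOS genes split 8 and 3 of 15 (11), ribosomal protein genes 2 and 9 of 20 (11) and WNT targets 5 and 3 of 9 (8). Of the neurogenins, NEUROG1 gave -0.44 (adjusted p = 0.62), and NEUROG2 had 1 count in each arm. Of the 12 histone genes listed, 0 could be matched to a tested gene.

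In induced neurons, 4776 genes were higher and 5028 lower in guide than in control libraries, 1430 and 1302 of them at least 2-fold. PRODH fell here too, from 10.1 ± 0.289 to 0.40 ± 0.403 CPM (-4.63, SE 0.28, adjusted p = 8.8e-17), while NTRK3 rose from 5.39 ± 0.321 to 18.1 ± 1.71 CPM (1.74, SE 0.14, adjusted p = 3.3e-13). TMEM120B fell from 335 ± 26.5 to 4.51 ± 0.652 CPM (-6.21, SE 0.11), and in iPS cells from 67.5 ± 4.22 to 1.19 ± 0.129 CPM (-5.81, SE 0.15). REM1, a small GTPase gene, had 2 counts against 369, a ratio of 0.00582 (0.000703 to 0.0212), and C2orf16 a ratio of 0.00808 (0.000203 to 0.0458). GDF3 and FZD9 were each at least 10.2-fold lower, GALNT6 at least 6.83-fold, FA2H at least 6.20-fold, ITLN2 at least 5.89-fold and FLVCR2 at least 5.58-fold lower. Among the rises, RFPL4B went from 1.22 ± 0.305 to 42.0 ± 4.1 CPM (5.12, SE 0.18), IFIH1, a sensor of double-stranded RNA, from 0.315 ± 0.121 to 11.1 ± 2.02 CPM (5.09, SE 0.28) and DCDC1 from 0.774 ± 0.527 to 18.7 ± 1.22 CPM (4.63, SE 0.23). SLC39A12, a zinc transporter gene, rose by 5.25 (SE 0.40), DUX4L9 by 4.97 (SE 0.31), MCOLN2 by 4.79 (SE 0.31) and TRIM49D2 by 4.77 (SE 0.45). KL, which encodes klotho, had a ratio of 48.0 (16.1 to 236) and TRIM51FP of 77.4 (13.4 to 3097). GRIN2B was at least 2.15-fold higher, a call lost without guide library 1 (adjusted p = 0.0789) or control library 1 (0.0596).

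5 lists passed camera in guide iN, and 0 with an estimated correlation. Core pluripotency genes fell at 21 of 26 and rose at 2 (23 adjusted over the list alone), with ZFP42 at -4.47, LEFTY2 at -4.39 and POU5F1 at -1.96, the last from 114 ± 11.9 to 29.2 ± 1.43 CPM (adjusted p = 3.3e-07, and adjusted p = 0.43 with an estimated correlation). Cell cycle genes fell at 21 of 24 and rose at 0 (21 adjusted over the list alone), with RRM2 at -1.82, CDK1 at -1.36 and TOP2A at -1.32 (adjusted p = 3.3e-07, and adjusted p = 0.43 with an estimated correlation). Of 15 p53 targets, 12 rose and 1 fell (13 adjusted over the list alone), with ZMAT3 at 2.11, TNFRSF10B at 1.91 and MDM2 at 1.70 (adjusted p = 2.1e-06, and adjusted p = 0.43 with an estimated correlation). Ribosomal protein genes fell at 19 of 20 (19 adjusted over the list alone), with RPS3 at -1.22 (adjusted p = 7.6e-07, and adjusted p = 0.613 with an estimated correlation). Glycolysis genes fell at 11 of 12 (11 adjusted over the list alone), with TPI1 at -0.90 and LDHA at -0.87 (adjusted p = 0.00205, and adjusted p = 0.613 with an estimated correlation). With a low-count filter of 1 count in total, 11 lists passed in place of 5.

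The neuronal gene lists did not pass in guide iN, and neither did the other lists below. Pan-neuronal genes rose at 0 and fell at 12 of 19 (12 adjusted over the list alone), with TUBB3 at -0.85 and MAPT at -0.63. NEUROG1, a driver of the induction, fell from 428 ± 78.9 to 202 ± 18.3 CPM (-1.08, SE 0.09). NEUROG2 gave -0.24 (adjusted p = 0.112). Whether NEUROG1 counts come from the induced copy was not tested. The arms may thus not have been induced alike, which cannot be told apart from the guide in the iN comparisons. Proneural factors split 4 and 8 of 18 (13 adjusted over the list alone), with DLL3 at -1.16, and peripheral and sensory neuron genes 4 and 10 of 14 (14), with PRPH at -1.44. Synapse genes split 8 and 6 of 25 (14), with PCLO at 1.31 and SNAP25 at 0.88, axon guidance genes 13 and 3 of 25 (18), with EPHB1 at 1.60, and transmitter receptors and transporters 9 and 6 of 22 (16), with GABRA2 at 2.78 and GRIN2A at -2.93. Neural progenitor genes split 1 and 7 of 11 (8), with NES at -0.75, glial genes 1 and 6 of 13 (7), with GJA1 at -1.47, and fibroblast and mesenchyme markers 6 and 4 of 11 (10), with ACTA2 at 2.93. HERVH-driven transcripts fell at 3 of 8 (3), with ESRG at -3.27, naive pluripotency genes split 2 and 2 of 9 (4), and domesticated ERV genes 0 and 1 of 5 (1). Mesoderm and endoderm markers split 2 and 3 of 9 (5), trophoblast and amnion markers 3 and 0 of 6 (3), interferon-stimulated genes 4 and 5 of 15 (9), integrated stress response genes 5 and 5 of 15 (10), heat shock genes 1 and 7 of 10 (8) and immediate early genes 1 and 6 of 11 (7). Retroelement silencing genes split 4 and 3 of 14 (7), KRAB zinc finger genes 13 and 4 of 22 (17), with ZNF486 at -4.53, nuclear OXPHOS genes 1 and 7 of 15 (8), mitochondrial genome transcripts 0 and 5 of 13 (7) and WNT targets 2 and 3 of 9 (6), with LEF1 at 2.77. Median, mean and test differed in sign for naive pluripotency genes (median -0.07, mean -0.13, test up), proneural factors (-0.18, 0.01, down), interferon-stimulated genes (0.12, -0.25, down), integrated stress response genes (-0.06, 0.08, up), immediate early genes (-0.33, 0.04, down), KRAB zinc finger genes (0.26, -0.08, up) and WNT targets (-0.20, 0.27, up).

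Without the guide, induction lowered pluripotency transcripts, without removing them, and raised neuronal ones: 7638 genes rose and 7772 fell, 4754 and 5015 of them at least 2-fold. CHRNA1, a muscle-type acetylcholine receptor gene, was at least 3825-fold higher in iN (9686 counts against 0), B3GALT2 at least 1842-fold, DRGX, a sensory neuron factor, at least 1151-fold and UNCX at least 857-fold higher. The metallothionein gene MT1H was at least 146-fold lower, MFSD6L at least 103-fold, APOBEC3B and CHP2 at least 102-fold each and CYP4F22 at least 71.7-fold lower. NEUROG1 rose from 0.302 ± 0.135 to 428 ± 78.9 CPM (10.48, SE 0.18), and NEUROG2 had a ratio of 889 (159 to 35142). POU5F1 fell from 1755 ± 107 to 114 ± 11.9 CPM (-3.95, SE 0.09), PRODH by 2.68 and NTRK3 by 0.52. Pan-neuronal genes rose at 19 of 19 (STMN2 8.09, DCX 6.52), proneural factors at 17 of 18 (NEUROD4 12.56, NHLH1 11.22), peripheral and sensory neuron genes at 13 of 14 (PRPH 9.59, ISL1 9.59), synapse genes at 21 of 25 (CPLX2 9.91) and axon guidance genes at 16 of 25 (SEMA6D 8.55). Adjusted over each list alone, 19, 18, 14, 24 and 23 changed. Camera gave adjusted p = 2.3e-08, 2.1e-07, 5.9e-05, 0.000126 and 0.0213, and with an estimated correlation adjusted p = 0.254, 0.135, 0.254, 0.332 and 0.332. Core pluripotency genes fell at 22 of 26 (TDGF1 -5.83), cell cycle genes at 23 of 24 (TOP2A -3.57), HERVH-driven transcripts at 8 of 8 (ESRG -6.51), fibroblast and mesenchyme markers at 11 of 11 (THY1 -4.09) and glycolysis genes at 12 of 12 (LDHA -3.23). Their adjusted p-values were 5.7e-06, 2.1e-07, 0.000725, 0.000765 and 0.000126, with 24, 24, 8, 11 and 12 changed adjusted over each list alone, and with an estimated correlation adjusted p = 0.298, 0.254, 0.254, 0.254 and 0.475. Ribosomal protein genes fell at 19 of 20, p53 targets at 12 of 15 and interferon-stimulated genes at 9 of 15, and mitochondrial genome transcripts rose at 11 of 13, with camera adjusted p = 5.9e-05, 0.00897, 0.0342 and 0.0185. Adjusted over each list alone, 19, 14, 12 and 11 changed, and with an estimated correlation these gave adjusted p = 0.481, 0.373, 0.254 and 0.659. Median and test differed in sign from the mean for heat shock genes (0.19, mean -0.10), and the median from both for KRAB zinc finger genes (0.0013, mean -0.00382). HERVH-int fell from 20087 to 179 CPM (-6.81, SE 0.14), LTR7 by 2.81 and HERVK-int by 1.39, while LTR5_Hs rose by 0.43, a call lost without iPS control library 1 (adjusted p = 0.0961) or iN control library 2 (0.0707). Of all subfamilies, 262 rose and 272 fell, with the largest rise for LTR71A (6.15) and MLT1A1-int (6.14).

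With the guide, induction raised 7902 genes and lowered 7302, 5263 and 4644 of them at least 2-fold, and 10 lists passed camera, 0 with an estimated correlation. B3GALT2 was at least 1322-fold higher, MAB21L1 at least 1265-fold and DRGX at least 993-fold higher, while CHRNA1 had a ratio of 11444 (2054 to 452063) and A2M of 14226 (2553 to 561927). GDF3 was at least 273-fold lower, CXCL6 at least 108-fold, FLVCR2 at least 101-fold and GALNT6 at least 94.1-fold lower. Pan-neuronal genes rose at 19 of 19 (STMN2 10.52), proneural factors at 18 of 18 (NEUROD4 11.74), peripheral and sensory neuron genes at 13 of 14 (POU4F1 11.41), synapse genes at 21 of 25 (CPLX2 6.79) and axon guidance genes at 19 of 25 (EPHA5 8.73). Their adjusted p-values were 2.0e-08, 4.6e-08, 0.000141, 0.000136 and 0.000889, with 19, 18, 14, 24 and 23 changed adjusted over each list alone, and with an estimated correlation adjusted p = 0.269, 0.118, 0.254, 0.324 and 0.257. Core pluripotency genes fell at 26 of 26, with POU5F1 from 1611 ± 45.0 to 29.2 ± 1.43 CPM (-5.78, SE 0.10), cell cycle genes at 23 of 24, HERVH-driven transcripts at 8 of 8, glycolysis genes at 12 of 12 and ribosomal protein genes at 20 of 20. Their adjusted p-values were 5.3e-10, 2.7e-09, 0.000482, 0.000481 and 1.5e-06, with 26, 24, 8, 12 and 20 changed adjusted over each list alone, and with an estimated correlation adjusted p = 0.254, 0.254, 0.262, 0.445 and 0.423. NEUROG1 rose by 9.84 and NTRK3 by 1.23, and PRODH fell by 2.22. For domesticated ERV genes the median was 0.30, with a mean of -2.43 and a test pointing down.

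**Figure D3:**
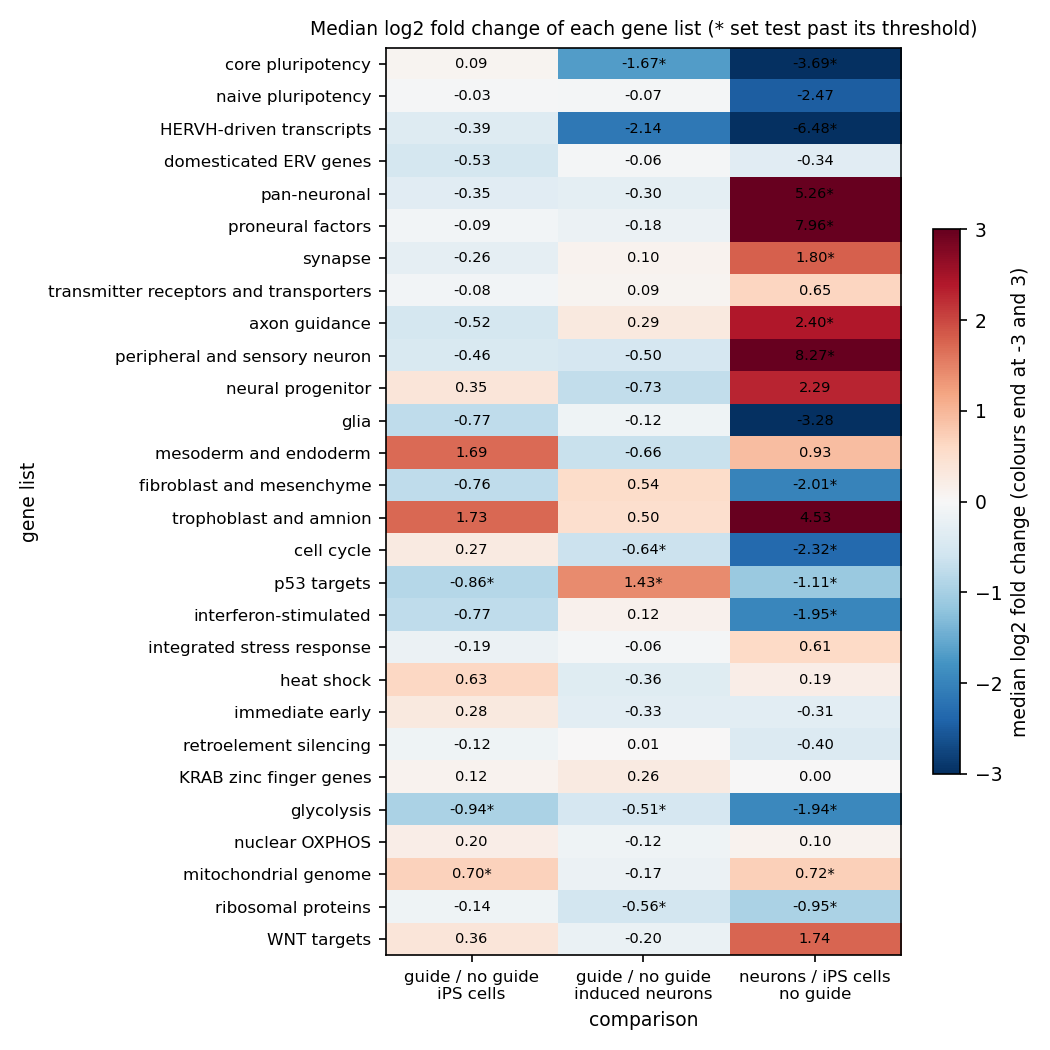
Median log2 fold change of each tested gene list in the guide comparisons of iPS cells and induced neurons and in induction without the guide, with an asterisk where camera passed at the preset correlation, which 0 lists did with an estimated one. Core pluripotency genes stand at 0.09, -1.67 and -3.69, and p53 targets at -0.86, 1.43 and -1.11.

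The difference between guide and control libraries itself differed between stages for 9918 genes, 5110 with a more positive and 4808 with a more negative change in iN than in iPS cells. p53 targets, of which 12 fell in iPS cells and 12 rose in iN, were more positive in iN at 14 of 15 (15 adjusted over the list alone), with ZMAT3 at 3.22 and CDKN1A at 2.66 (adjusted p = 1.4e-06, and adjusted p = 0.522 with an estimated correlation). Core pluripotency genes were more negative at 20 of 26 (24 adjusted over the list alone), with ZFP42 at -4.59 and POU5F1 at -1.84 (adjusted p = 1.8e-05, and adjusted p = 0.522 with an estimated correlation). Cell cycle genes were more negative at 17 of 24 (19 adjusted over the list alone), with RRM2 at -3.25 (adjusted p = 5.1e-06, and adjusted p = 0.522 with an estimated correlation). NTRK3 differed by 1.75 (SE 0.20, adjusted p = 2.9e-09), and for PRODH the difference of 0.47 (SE 0.51) did not pass (adjusted p = 0.466). Both stages shared 1728 rising genes, where 1332 would be shared by independent draws, and 2225 falling genes against 1734, while 2524 of the 6477 genes that passed in both stages went opposite ways. Across genes the log2 fold changes of both stages correlated at r = 0.193 (Spearman's rho 0.161), and genes are not independent replicates. Among subfamilies, 461 were more positive and 34 more negative in iN, or 152 and 207 with repeat-count scaling. Summed over its lines, HERVK-int fell less in iN by 1.73 (SE 0.16, adjusted p = 1.1e-23), while of its 19 single loci joined to LTR5_Hs 3 were more positive in iN, 1 was more negative and 15 did not pass. LTR5_Hs differed by 0.33 (adjusted p = 0.114), or by -0.23 with repeat-count scaling and by 0.43 without iN guide library 2, which passed (adjusted p = 0.00221).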

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

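The tests below of equal depth, of the share of HERVH loci and of the core pluripotency genes were chosen after the results were seen. Exact and bootstrap intervals in this part and under Other observations treat bins, loci or genes as independent, which they are not. Apart from the SE of HERVH-int in its comparison with core pluripotency genes, these intervals hold no spread between libraries. Each result here was listed because the guide effect differed between iN and iPS cells by a test of that difference, given as the iN minus the iPS log2 fold change. It covered 9918 genes and 495 repeat subfamilies.

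Among subfamilies, HERVK-int differed by 1.73 (iPS -2.10, iN -0.37), HERVK3-int by 1.19 (-0.47 and 0.72), SVA_C by 1.16 (-0.98 and 0.18) and LTR12C by 0.83 (-0.10 and 0.73), each also past the threshold with repeat-count scaling. HERVH-int differed by 0.63 (-1.37 and -0.74), LTR7 by 1.01 (-0.80 and 0.21), SVA_E by 0.92 (-0.78 and 0.14) and LTR5A by 0.74 (-0.09 and 0.65), calls that ended with that scaling at 0.07, 0.46, 0.36 and 0.19 (adjusted p = 0.383, 0.0801, 0.134 and 0.578). The LTR5A call was also lost without iPS guide library 2 (adjusted p = 0.144), iPS control library 1 (0.0586) or 2 (0.068) or iN control library 1 (0.0706). MER34-int differed by 2.86 (-1.13 and 1.72), HERVI-int by 2.81 (-0.82 and 1.99), MER110 by 2.72 (-0.63 and 2.09), ERV24_Prim-int by 2.66 (-1.17 and 1.48) and LTR10G by 2.85 (-1.59 and 1.26), the last lost without iPS control library 2 (adjusted p = 0.0849). In the other direction, L1PA10 differed by -1.96 (3.08 and 1.12), with 1302 of its 1437 CPM in guide iPS cells at 1 locus. LTR70 differed by -1.88 (1.44 and -0.44), Kanga1a by -1.86 (1.18 and -0.67), L1PA15-16 by -1.75 (1.48 and -0.27) and MER66D by -1.57 (0.43 and -1.13). For HERVK-int, the provirus on chromosome 22 at 18926187 gave -5.81 in both stages. That provirus held 99.97 of 225.7 HERVK-int CPM in iPS controls but 5.24 of 86.16 in iN controls. The HERVK-int difference therefore also reflects which proviruses were counted in each stage.

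Among gene lists, the median difference was 1.91 for p53 targets, -1.43 for core pluripotency genes and -0.90 for cell cycle genes. Each of these gave a camera adjusted p = 0.522 with an estimated correlation. Heat shock genes had -0.81, with 8 of 10 more negative in iN (camera adjusted p = 0.0022, and adjusted p = 0.522 with an estimated correlation), and mitochondrial genome transcripts -1.05, with 10 of 13 (0.0022, and 0.773 with an estimated correlation). Ribosomal protein genes had -0.46, with 13 of 20 (adjusted p = 0.00463, and adjusted p = 0.797 with an estimated correlation), and nuclear OXPHOS genes -0.37, with 11 of 15 (0.0385, and 0.686 with an estimated correlation). The nuclear OXPHOS call was lost without iN guide library 1 (adjusted p = 0.0535) or iN control library 2 (0.0538).

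Among genes, IFIH1 differed by 6.16 (iPS -1.07, iN 5.09), NTRK3 by 1.75 (-0.00 and 1.74), POU5F1 by -1.84 (-0.12 and -1.96), ZNF587 by 1.15 (-1.08 and 0.06) and ZNF417 by 0.74 (-0.45 and 0.29). In the genes that follow, at least 1 group had at most 5 counts, so the fitted difference depends on the prior count. ANKRD33 stood at 12.31, LAPTM5 at 7.75, ALDH8A1 at 7.30, SLC4A5 at 7.16, LAMB2P1 at 6.93, EXOC1L at 6.78, TBC1D26 at 6.60, SGCD at 5.87 and LMO1 at 5.76. REM1 stood at -9.71, GDF3 at -7.81, H1-5 at -7.55, CMKLR2 at -7.53, GPR12 at -6.81, FLVCR2 at -6.32, GALNT6 at -5.66, TMEM271 at -5.45 and TIMP4 at -5.45. The EXOC1L call was lost without iPS control library 1 (adjusted p = 0.0936), and the TMEM271 call without iPS guide library 1 (1), iPS control library 1 (0.0603) or 2 (0.0752).

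Most repeat subfamilies were higher in guide libraries, more so in iN. At equal gene depth, guide libraries held a count at 1.70 times as many repeat lines in iPS cells (1.68 to 1.72 over pairs of libraries) and 2.06 times in iN (1.83 to 2.30), which argues against sequencing depth as the cause. Genomic DNA spread evenly over the genome would add as much per kb everywhere. The excess was larger in the 1-Mb bins most counted in the other stage's controls than in the least counted ones. It was 6.89 times as large in iPS cells (bootstrap interval 5.86 to 8.26) and 5.06 times in iN (4.60 to 5.82). That argues against even genomic DNA as the whole cause. A smaller even part stays open, since the least counted bins also held an excess. Whether RNA of the same regions rose in proportion stays open, since the log2 ratio was larger in the least counted bins by 0.71 in iPS cells (0.60 to 0.84) and 0.82 in iN (0.75 to 0.90), between the bounds set for either answer. A difference between the transduced lines or in library preparation falls together with the guide, so it may also lie behind the pattern, and no biological explanation was tested apart from it.

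HERVH was lower in guide iPS cells although the guide was made for LTR5_Hs. A few abundant loci are argued against as the whole cause, unless similar loci share reads. Of the 575 tested HERVH-int loci, 92.0% had a negative change (exact 95% interval 89.5% to 94.1%). The handling of reads that map to several places is not given, so loci may move together. Spread of repression from annotated LTR5_Hs elements is argued against too, since the 411 loci over 1 Mb from any of them had a median of -1.24 (bootstrap interval -1.31 to -1.14). A loss of pluripotent cells as the whole cause would lower the core pluripotency genes about as much, while their median, 0.0927 (bootstrap interval -0.26 to 0.37), lay 1.46 above the change of HERVH-int (1.06 to 1.81), which argues against it. A small loss that adds to the fall could still lie within that interval. An effect of the guide elsewhere or a different state of the transduced line was not tested.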

How the results depend on the processing

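The non-legacy fit, the other assignment of merged lines and the filter to loci counted in the stage were chosen after seeing the data, and each alternative changed 1 choice. Summed over alternatives, directions and sides of the threshold stayed in 9575 comparisons of named genes with the reported value, against 76 weaker, 7 stronger and 16 reversed, in 488 of gene lists (43 weaker), in 1441 of subfamilies (41 weaker, 17 stronger, 25 reversed) and in 450 of single loci. The cause was not tested for any shift below except where the alternative itself removes samples or features. NTRK3 in iPS cells turned from -0.00 to 0.0116 with RLE scaling, 0.0708 with only the 2 groups fitted and 0.00928 with DESeq2. With other low-count filters, 11 gene lists passed in iN and 3908 (iPS) and 3569 (iN) repeat loci, and DESeq2 called 3052 and 2049 loci. With at least a 2-fold change also required, gene counts fell to 4102 (iPS), 2732 (iN), 9769 (iN against iPS without the guide), 9907 (with it) and 4325 (interaction). With an estimated correlation, and so fewer degrees of freedom, camera called 0 gene lists in each of the 5 comparisons. Scaled by repeat counts, 381 subfamilies passed in iN, and LTR5_Hs there stood at -1.07. In iN this scaling turned LTR5A to -0.39, LTR5B to -0.53, SVA_C to -0.87, SVA_E to -0.91, LTR7 to -0.83, L1HS to -0.44, LTR12C to -0.32, HERVK9-int to -0.50 and HERVK3-int to -0.32. In the interaction it turned LTR5_Hs to -0.23, SVA_B to -0.46, SVA_D to -0.21 and SVA_F to -0.25. The loci near LTR5_Hs gave -0.27 within 10 kb in iPS cells (adjusted p = 0.0413) and -0.17 within 200 kb in iN (0.0713), while those near LTR7 in iN gave -0.11 among loci counted there (0.252). With merged lines counted as LTR5_Hs, HERVK-int stood at 0.0773 in iPS cells and 0.50 in iN, and LTR5_Hs at -0.63 in iN. Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 2960 to 7002 repeat loci in iPS cells and 3281 to 6684 in iN. In iPS cells it gave ranges of -0.44 to -0.27 for LTR5_Hs, -0.22 to 0.0362 for LTR5A, -0.0340 to 0.0232 for NTRK3, -0.88 to 0.0499 for NEUROG1 and -2.14 to 2.46 for NEUROG2. In iN the ranges were -0.13 to 0.0718 for LTR5_Hs, -0.0102 to 0.28 for SVA_E, -0.22 to 0.00492 for SVA_F, -0.0113 to 0.40 for LTR7, -0.52 to 0.49 for LTR7Y, -0.0800 to 0.33 for ERV3-1 and -0.0703 to 0.18 for ZNF587. For the interaction they were -0.16 to 0.0655 for LTR5B, -0.20 to 0.00835 for L1HS, -2.70 to 1.90 for NEUROG2, -1.28 to 1.22 for PRODH, -0.30 to 2.52 for CDX2 and -0.25 to 0.00634 for ZNF10. SVA_C in iN against iPS cells without the guide ranged from -0.0385 to 0.0763. With replicate number as a block, 11718 genes passed in iPS cells and 9728 in iN. Line as a block cannot be estimated within a stage and was not run there. Simulated at these depths with most features unchanged, 11.9% of loci with a 2-fold change in iPS cells were recovered and 71.6% of genes.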

Other observations

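All tests in this part were chosen after the results were seen, and the lists of DUX4 targets and imprinted genes were composed then. Many genes known as targets of DUX4, a transcription factor of early embryos, were higher in guide libraries of both stages. Of 55 listed targets, 37 were tested, in a list that holds genes whose rise had been seen. Of these 37, 29 rose and 1 fell in iPS cells (median 3.0). In iN 33 rose and 1 fell (median 3.47), and 27 rose in both. Of 32 targets not seen before, 14 were tested. Of these 14, 6 rose and 1 fell in iPS cells (median 0.72), 10 rose and 1 fell in iN (median 1.98), and 4 rose in both. The low-count filter can keep a gene through guide libraries alone, so these shares do not extend to untested targets. ZSCAN4 went from 0.667 ± 0.183 to 4.74 ± 0.478 CPM in iPS cells (2.84, SE 0.27, n = 2) and from 0.723 ± 0.0307 to 14.1 ± 1.83 CPM in iN (4.28, SE 0.23). TRIM43 rose by 3.49 and 3.68, KDM4E by 3.56 and 3.88, LEUTX by 2.32 and 3.28, SLC34A2 by 1.94 and 3.92 and CCNA1 by 0.82 and 2.76.

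A background that raises weakly expressed genes alike may explain such rises. The medians of the 14 targets lay at the 99.5th percentile in iPS cells and the 100th in iN of 10000 random lists matched on expression. They thus shifted more than tested genes of like expression. This does not settle the question, since that list was composed after the strongest changes were known. The low-count filter also kept some of these targets through guide libraries alone. Of 7 tested targets that have no near-identical copies and were not seen before, 6 rose in iN, or 85.7% (exact 95% interval 42.1% to 99.6%). Of all genes, 25.3% rose there. KHDC1L (76 counts in guide iN, 9 in control iN) and ZNF280A (42 and 12) passed the low-count filter through guide iN alone. The filter thus favoured a rise, so this share does not settle whether reads shared by such copies are the whole cause there. In iPS cells 3 of the 7 rose, or 42.9% (9.9% to 81.6%), against 27.9% of all genes, which leaves shared reads open. Together with the 4 seen before, 6 of 11, or 54.5% (23.4% to 83.3%), rose in both stages. A candidate explanation is DUX4 activity in the guide lines, which was not tested apart from a difference between lines.

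Of 31 tested imprinted genes, 11 rose and 7 fell in iPS cells and 8 rose and 10 fell in iN. Their medians lay at the 80.5th and 20.4th percentile of matched random lists, so the list did not shift in a common direction. A median over members that go both ways cannot tell whether imprinted genes changed more than others. In both stages 3 rose and 3 fell: KCNQ1OT1 (2.74 in iPS cells and 2.28 in iN), SNURF (1.89 and 1.92) and PEG3 (1.11 and 1.04) against IGF2 (-2.33 and -0.98), TRAPPC9 (-0.86 and -0.51) and PEG10 (-0.29 and -0.31).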
